A study of Mus musculus with 2 samples.

How the data were processed

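Spleen cells sorted for CD45 were profiled in 2 libraries, 1 uninfected and 1 Pb-infected, with a droplet kit for 3' ends of transcripts per the labels' protocols. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and the genome build mm10, whereas the header of the deposited matrices names Cell Ranger 6.1.2; which of these made the counts is not given in the sources used here. Every barcode in the deposited matrices had at least 500 UMIs.

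Barcodes were kept with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs, which left 13818 uninfected and 12722 infected barcodes. Doublets were predicted per library with Scrublet as run by scanpy 1.11.5, with expected rates of 11.1% and 10.2%, and 833 and 518 barcodes were removed (6.03% and 4.07%). Both libraries were clustered together without integration on 2000 variable genes that left out the lists for interferon responses, MHC class I, replication, mitosis and immediate early genes, and mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor segment genes. Clustering used 30 components (scikit-learn 1.9.0), 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

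Clusters were named X-like from markers fixed before the data were examined, together with the gene lists and the rule for named genes. The scoring rule was set after seeing the data: a cluster took the class with the highest mean log2 marker level over the median cluster, needed a score of 1.5, a margin of 0.25 over the next class, at least 3 detected markers and no class with more markers among its 10 leading genes. A cluster also failed if its median UMIs lay below the library median divided by 3 and none of its own markers was among those leading genes, as in cluster 22. Clusters of at least 120 cells that failed were clustered once more at resolution 0.5 and split where this gave more than 1 part, which it did not in cluster 22. The rule that divides T clusters was also set after seeing the data, and 3 versions were tried. The first compared Cd4 with the sum of Cd8a and Cd8b1 at a ratio of 5 and put cluster 18, which carries both Cd4 and Cd8a, in CD8 T. The second used a ratio of 10 on that sum and put every CD4 T cluster in mixed T; class shares, named genes and gene lists had been seen under it when it was dropped. The third, used here, compares Cd4 with Cd8a alone at a ratio of 5. The results of the first 2 are given as added alternatives.

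Class shares carry exact Clopper-Pearson 95% intervals. Within the 7 classes with at least 200 kept cells in each library, raw counts were summed per library and class and given as CPM, the counts scaled to a fixed total, with the ratio of infected over uninfected and an exact conditional binomial 95% interval. No test was made, since each group is 1 library. The genes named had at least 50 CPM and 50 UMIs in the library where they were higher and were the 10 with the highest and the 10 with the lowest ratio, ranked by the interval bound nearest 1, in the 4 classes with the most cells, and 5 and 5 in the others. Left out were mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor segment genes, unnamed gene models, and genes under 10% of the highest CPM of any class, where free RNA can set the value. The 4 most abundant measured members of each list, and immunoglobulin constant genes, may be named too. The members named from the lists for other cell types, and Hbb-bs in cluster 5, were chosen after their values were seen.

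A list member was measured with a mean of at least 10 CPM and at least 20 UMIs in both libraries together; medians needed 5 measured members, and a count of 0 was set to a floor of 3 counts. Intervals of list medians came from 200 Poisson redraws. In all, 23 lists and 5 lists of transcripts from other cells, platelets or sex-linked genes were used; Mx1, Mx2 and Clec7a were not found by name among the features. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. Coordinates came from GENCODE M21 on GRCm38.

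The interval and list functions were tested on simulated counts for the B comparison, with 200 genes changed by known folds. The simulated counts were Poisson draws of the class sums, the error that the intervals assume, so they check the computation only. Variation between cells was not simulated, and the intervals do not cover it. Of 11584 genes, 95.5% had intervals that held the simulated ratio. All 50 genes changed 4-fold up were recovered, as were 98.0% of the 50 lowered to 0.5. Of the 11384 unchanged genes, 11.9% had an interval that left out 1, because the changed genes move the total behind CPM by a log2 ratio of -0.05; against that shifted value it was 4.49%. An interval of a CPM ratio close to 1 therefore does not show that a gene differs.

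Alternatives chosen after seeing the data were the first 2 T rules, the counting of cluster 5 as B, cluster 8 alone for NK-like cells, cluster 7 alone for neutrophil-like cells, B-like cells without their cycling cluster, and cDC-like cells without those of 10 or more Ngp UMIs. The alternatives chosen before were other cell filters, doublets kept, other resolutions, separate clustering, all variable genes, assignment of each cell by its own markers, a lymphocyte denominator, other scalings, equal weight per cell, other CPM minimums and other thinning depths.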

Results

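Single-cell RNA libraries were made from spleen cells of wild-type mice, 1 library from uninfected mice and 1 from Pb-infected mice. The infected animals had received 10000 iRBCs into the peritoneum and spleens were taken on day 5; cells were sorted for CD45, the common leukocyte surface protein. The uninfected library held 14477 barcodes with 52640079 UMIs, and the infected library held 13399 barcodes with 58298646 UMIs. The median was 2955 UMIs per barcode in the uninfected library and 3145 in the infected library. After filtering and removal of predicted doublets, 12985 uninfected and 12204 infected cells were kept. With 1 library per group there is no replicate check, and the labels do not say how many mice each library holds. All intervals below are 95% intervals that cover counting error only.

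The first comparison asks how the makeup of the sorted spleen cells differed between the libraries. Neutrophil-like cells made up 6.36% of uninfected cells (exact binomial interval 5.95 to 6.79%) and 3.27% of infected cells (2.96 to 3.60%), a log2 ratio of -0.96 (-1.14 to -0.79). CD4 T-like cells were also lower, at 16.1% against 11.5%, a log2 ratio of -0.49 (-0.59 to -0.39). Conventional dendritic (cDC-like) cells were 3.87% in the uninfected and 2.16% in the infected library, a log2 ratio of -0.84 (-1.06 to -0.63). Macrophage-like cells numbered 270 and 146, a log2 ratio of -0.80 (-1.10 to -0.50). B-like cells were the most numerous class and were higher in the infected library, at 41.6% (40.8 to 42.5%) against 47.7% (46.8 to 48.6%). Monocyte-like cells, at 7.04% and 7.34%, and NK-like cells, at 4.32% and 4.28%, had intervals of the log2 ratio that included 0, as did CD8 T-like cells at 9.66% and 8.92%. The CD8 T-like log2 ratio of -0.12 was 0.12 when cluster 18 was counted as CD8 T. A single cluster of cycling and activated T cells, cluster 18, carried both Cd4 and Cd8a transcripts and was kept apart as mixed T. It held 60 uninfected cells (0.462%) and 253 infected cells (2.07%). Its median depths were 11280 and 19584 UMIs, against 3187 and 3014 in CD4 T-like and 4023 and 4416 in CD8 T-like cells. Fewer doublets were predicted than the expected rates, and whether doublets of T cells remain in this cluster was not tested. The mixed T log2 ratio of 2.17 was 0.11 when all variable genes were used and 0.60 with predicted doublets kept, where other clusters took that name too. It was -0.29 under another rule for dividing T cells and -0.36 when each cell was named by its own markers, which put 1548 uninfected and 1136 infected cells in the class. Naming by own markers called a T cell mixed when its Cd4 count equalled its summed Cd8a and Cd8b1 count. This includes cells with none of these transcripts, so that class is unlike cluster 18. With all variable genes, a cluster of 67 uninfected and 261 infected cells was joined in the class by one of 388 and 199, and with doublets kept, a cluster of 64 and 265 by one of 322 and 274. When each library was clustered on its own, only 30 infected cells were named cDC-like, a log2 ratio of -3.97, and the macrophage-like log2 ratio was 0.17.

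**Figure D1:**
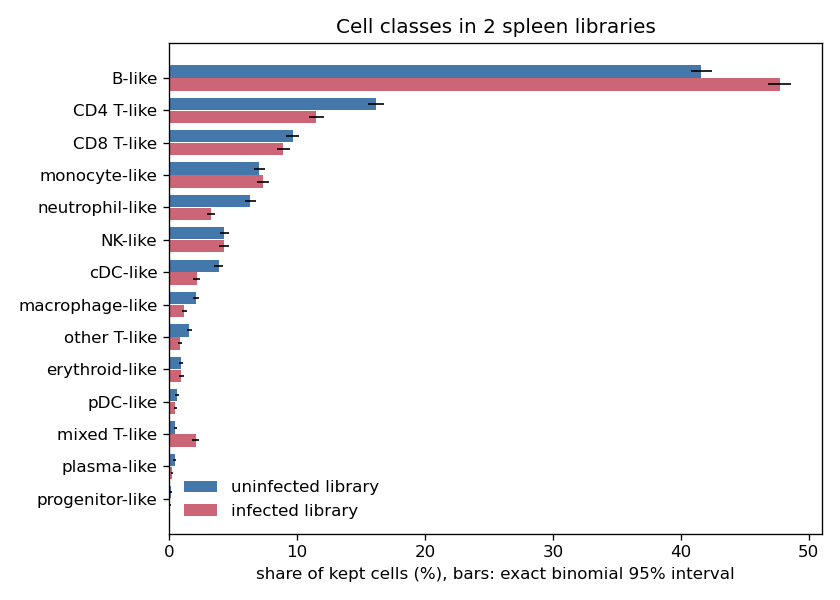
Share of kept cells (%, horizontal axis) in each cell class (vertical axis) for the uninfected and the infected library; lines are exact binomial 95% intervals. B-like cells stand at 41.6% and 47.7%, and neutrophil-like cells at 6.36% and 3.27%.

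Clusters that failed the naming rule were left out of the classes. Cluster 5 had B cell markers but haemoglobin or activation genes among its leading genes, and it held 2.56% of uninfected cells and 7.23% of infected cells. Haemoglobin genes led its part of 97 uninfected and 370 infected cells. Across cluster 5, Hbb-bs stood at 2000 CPM in uninfected and 0.267 CPM in infected cells. The infected cells of that part were thus left out although they held little of this RNA. The other unnamed clusters held 2.16% and 1.79%. Counting cluster 5 as B raised the log2 ratio of the B share from 0.20 to 0.31. The kept cells all had at least 500 UMIs. Among the named classes, median depth was lowest in erythroid-like cells, at 976 and 1117 UMIs, macrophage-like cells, at 1194 and 1255, and neutrophil-like cells, at 1844 and 1600.

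The second comparison asks which genes differed within each class. In B-like cells, genes of the interferon response were higher in the infected library. Iigp1, an interferon-inducible GTPase, stood at 5.60 CPM in the uninfected and 159 CPM in the infected library, a ratio of 28.3 (23.1 to 35.1). Socs1, an inhibitor of cytokine signalling, was 13.3-fold higher (12.3 to 14.5), and Socs3 11.1-fold higher (9.22 to 13.6). The guanylate-binding gene Gbp7 stood at 41.2 and 248 CPM, Gbp6 and Gbp4 were 5.13-fold and 4.92-fold higher, and Ifit2, Ifi47 and Igtp 5.04-fold, 4.48-fold and 4.38-fold higher. Lower in the infected library were Id3 (ratio 0.388, 0.368 to 0.409), Fcer2a, which encodes the low-affinity IgE receptor CD23 (0.389, 0.366 to 0.412), Cd55 (0.475), Pdcd4 (0.492) and Notch2 (0.488). All 23 measured members of the interferon-gamma list were at least 2-fold higher, with a median log2 ratio of 2.16, and 22 of 32 measured members of the type I interferon list were, with a median of 1.24. In the B cell activation list, Cd69 stood at 236 and 524 CPM and Ncl at 447 and 629 CPM. Of 16 measured members, 2 were at least 2-fold higher, and the list median was 0.44. These values leave out the unnamed cluster 5, with 332 uninfected and 882 infected cells. Its leading genes included the list members Cd83, Il4i1 and Myc, so the median does not cover those cells. MHC class II genes had a median of -0.10, which was 0.0020 under median-ratio scaling; H2-Ab1 stood at 2240 and 1877 CPM. Different clusters held most B-like cells in the 2 libraries: cluster 1 held 3587 uninfected and 455 infected cells, and cluster 0 held 295 and 3867.

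The gene and class pairs whose shares of cells with a UMI are given here were chosen after their values were seen. Fcer2a was detected in fewer B-like cells of the infected library. After thinning to 1000 UMIs, 19.8% of uninfected cells (18.7 to 20.9%) and 8.61% of infected cells (7.90 to 9.36%) had a UMI; without thinning the shares were 40.1% and 20.9%. Thinning left out 69 uninfected and 60 infected B-like cells, and 58 and 34 CD4 T-like cells. In CD4 T-like cells, which should lack it, the thinned Fcer2a shares were 0.441% and 0.511%. Median depths were 2564 and 2793 UMIs in B-like cells and 3187 and 3014 UMIs in CD4 T-like cells.

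In CD4 T-like cells, Ifng, the gene of interferon-gamma, had the highest ratio of the genes taken by the naming rule, 9.28 (7.10 to 12.3), at 9.06 and 84.1 CPM. Cluster 10, with 482 of 2097 uninfected and 302 of 1404 infected cells, carried 90.5% and 89.3% of the Ifng UMIs. The leading genes of cluster 10 included the regulatory T cell markers Foxp3, Ctla4, Il2ra, Ikzf2 and Tnfrsf18. They also included Izumo1r, Maf and Icos of the Tfh list. In the whole class, 33 uninfected and 78 infected cells had an Ifng UMI. Whether these cells carried the regulatory markers was not tested. A single infected cell carried 36.6% of the 393 infected Ifng UMIs of the class. The Ifng log2 ratio of 3.21 was 1.82 when each cell had the same weight and 2.55 under the strict cell filter. Iigp1 was higher by a log2 ratio of 2.24 (2.10 to 2.37), Ifit3 4.36-fold, Gbp2 3.98-fold and Isg15, a ubiquitin-like interferon-induced protein, 3.85-fold. Lower were Id3 (111 and 42.4 CPM), Dapl1 (0.454), Emp3 (0.560) and Thy1 (0.552). The interferon-gamma list had 21 of 22 measured members at least 2-fold higher and a median of 1.62; the type I list had 22 of 33 and a median of 1.15. Of the Th1 genes, 2 of 10 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.40; Hopx stood at 50.9 and 78.7 CPM. Ccl5, at 209 and 48.8 CPM, and Gzmb, at 11.9 and 138 CPM, were under 10% of their NK-like levels, where free RNA can set the value. The Ccl5 level was 4.21 and 1.84 times that of B-like cells, which should lack it, and the Gzmb level 5.56 and 6.92 times. Cluster 10 carried 81.7% and 56.1% of the Ccl5 UMIs and 88.0% and 88.2% of the Gzmb UMIs. The list of naive and resting T cell genes had a median of 0.05. Cluster 2 held most CD4 T-like cells in both libraries.

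In CD8 T-like cells, Gadd45g was 5.32-fold higher (4.13 to 6.94) in the infected library, Iigp1 4.40-fold (3.76 to 5.17), Isg15 3.49-fold and Ly6a, the surface protein Sca-1, 3.31-fold (3.11 to 3.52). The chemokine gene Ccl5 was lower, at 1821 and 682 CPM, a ratio of 0.375 (0.361 to 0.389), as were Ahnak (log2 ratio -1.84), Cxcr4 (0.369) and Thy1 (0.549). Ccl1 had 424 UMIs in the uninfected and 0 in the infected library, at least 145-fold lower against a floor of 3 counts, but 3 cells carried all of its UMIs. The median of the DNA replication list was 0.87 and that of mitosis 1.14, while naive and resting T cell genes had a median of -0.28. The interferon-gamma list median of 1.23 was 0.86 and the type I list median of 0.82 was 0.52 when cluster 18 was counted as CD8 T; the Ahnak log2 ratio was then -0.75 and the DNA replication median 1.51. With libraries clustered apart the mitosis median was 1.81. Cluster 4 held most CD8 T-like cells in both libraries. Cluster 9 held 467 uninfected and 361 infected cells. Its leading genes included the gamma-delta T cell markers Trdc and Tcrg-C2 beside Cd8a and Cd8b1. Ccl5 UMIs were seen in 469 uninfected and 326 infected cells of the class. How the 2 clusters share these differences was not tested.

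In NK-like cells, Ly6a was higher in the infected library by a log2 ratio of 3.97 (3.70 to 4.26) and Gadd45g 8.99-fold (6.95 to 11.8); Csf2, the gene of the growth factor GM-CSF, was 6.92-fold higher (4.47 to 11.2). With predicted doublets kept, the log2 ratio of Ly6a was 2.43. Lower were Klrb1a (0.194, 0.160 to 0.235), Tspan32 (0.208), Ypel3 (0.266), Mxd4 (0.271) and S100a4 (0.283). Of the cytotoxic effectors, Gzmb, which encodes granzyme B, stood at 1232 CPM in the uninfected and 2813 CPM in the infected library and Ifng at 186 and 645 CPM, whereas Ccl5 stood at 16008 and 5726 CPM. The list median was -0.16, with 2 of 20 at least 2-fold higher and 1 at least 2-fold lower, and 0.0019 in cluster 8 alone. The DNA replication list had a median of 1.05 with 10 of 20 measured members at least 2-fold higher, and glycolysis a median of 0.76. These medians mix 2 clusters: the cycling cluster 20 held 62 uninfected and 180 infected cells, and cluster 8 held 499 and 342. In cluster 8 alone the replication median was 1.22 and that of glycolysis 0.53. NK-like cells also differed in depth, with medians of 3974 and 6431 UMIs. Thinned to 1000 UMIs, Ifng was seen in 18.8% of uninfected cells (15.6 to 22.3%) and 31.2% of infected cells (27.2 to 35.4%), and Gzmb in 60.0% and 76.3%; unthinned shares were 43.5% and 73.8% for Ifng and 84.5% and 96.2% for Gzmb. B-like cells, which should lack both, had thinned shares of 0.0750% and 0.712% for Ifng and 0.225% and 1.98% for Gzmb, at median depths of 2564 and 2793 UMIs. Thinning left out 8 uninfected and 3 infected NK-like cells, and 69 and 60 B-like cells.

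Monocyte-like cells had the interferon-induced chemokine genes among those with the highest ratios. Cxcl9 was 21.2-fold higher (19.2 to 23.4) in the infected library, at 77.8 and 1649 CPM, and Cxcl10 16.5-fold (15.7 to 17.4), at 281 and 4630 CPM. A single uninfected cell carried 33.7% of the Cxcl9 UMIs of that library's class. Serpina3g was 18.4-fold higher (15.8 to 21.5), Acod1, which encodes the enzyme that makes itaconate, stood at 9.35 and 140 CPM, and Il1rn, the interleukin-1 receptor antagonist, was 13.8-fold higher (10.8 to 18.0). Lower were Apoe (0.0891, 0.0774 to 0.102), Apoc2 (0.108), Cx3cr1 (0.215), Fn1 (0.258) and Klf4 (0.290). The inflammatory cytokine list had a median of 1.51, with 9 of 14 measured members at least 2-fold higher, and MHC class II presentation a median of 1.18 with 7 of 10; Cd74 stood at 1705 and 4190 CPM and H2-Aa at 807 and 1982 CPM. Thinned to 1000 UMIs, Cxcl9 was seen in 2.20% of uninfected cells (1.35 to 3.38%) and 44.0% of infected cells (40.7 to 47.3%), against unthinned shares of 3.39% and 58.1%, at median depths of 6256 and 6527 UMIs. B-like cells, which should lack Cxcl9, had thinned shares of 0.131% and 0.781%, at 2564 and 2793 UMIs. Thinning left out 5 uninfected and 3 infected monocyte-like cells, and 69 and 60 B-like cells. The class was held by different clusters: cluster 12 held 642 uninfected and 20 infected cells, cluster 11 held 32 and 701, and cluster 16 held 240 and 175. Cluster 11 took the monocyte name by its marker score of 3.43, against 1.70 for macrophage. None of its 10 leading genes was a monocyte marker. In GENCODE M21 on GRCm38, Cxcl9 lies on chromosome 5 from 92321347 to 92328079 and Cxcl10 on chromosome 5 from 92346638 to 92348889, both on the minus strand and protein-coding.

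In neutrophil-like cells, Cxcl10 stood at 35.5 CPM in the uninfected and 2819 CPM in the infected library, a ratio of 79.5 (62.2 to 103), and Socs1 at 79.6 and 1534 CPM, a log2 ratio of 4.27 (4.02 to 4.52). Trim30c stood at 6.99 and 140 CPM, and Gbp4 had a log2 ratio of 3.72, which was 3.05 with predicted doublets kept. Lower were Wfdc17 (0.180, 0.164 to 0.198), Lrg1 (0.194), Cd244a (0.214) and Igfbp6 (0.0759, 0.0324 to 0.152). The neutrophil granule list had a median of 0.02 in the whole class, with 0 of 10 at least 2-fold higher and 3 at least 2-fold lower. Camp stood at 9438 and 13647 CPM and Lyz2 at 3143 and 3028 CPM. Cluster 24, with 37 uninfected and 25 infected cells, carried 99.8% and 99.9% of the Camp UMIs; in cluster 7 alone 0 of 5 measured members were higher and the median was -0.54. Thinned to 1000 UMIs, Cxcl10 was seen in 1.65% of uninfected cells (0.879 to 2.80%) and 44.2% of infected cells (39.1 to 49.3%), against unthinned shares of 2.78% and 47.9%, at median depths of 1844 and 1600 UMIs. CD4 T-like cells, which should lack Cxcl10, had thinned shares of 0.785% and 5.77%, at 3187 and 3014 UMIs. Thinning left out 36 uninfected and 21 infected neutrophil-like cells, and 58 and 34 CD4 T-like cells. Cluster 7 held most neutrophil-like cells in both libraries, but at resolution 2 different clusters held them, one with 751 uninfected and 18 infected cells and another with 38 and 356.

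In cDC-like cells, Iigp1 was 35.0-fold higher (24.5 to 51.5) in the infected library, Cxcl10 24.1-fold (19.5 to 29.9), Socs1 9.39-fold (7.70 to 11.5), Gbp2 8.44-fold (7.01 to 10.2) and Cxcl9 6.89-fold (6.18 to 7.70). Lower were Cd209a, a lectin of type 2 dendritic cells (0.0973, 0.0634 to 0.143), Clec4a3 (0.167), H2-M2 (0.213) and Egr1 (0.277). MHC class II genes had a median of -0.34 in this class. H2-Aa stood at 10002 and 7695 CPM and Cd74 at 14436 and 12525 CPM. Cd209a was seen in 7.44% of uninfected cells (5.21 to 10.2%) and 2.90% of infected cells (1.18 to 5.89%) after thinning, and in 19.5% and 4.94% without it; of 2039 uninfected and 1370 infected CD4 T-like cells, 0 had a thinned UMI, with exact upper bounds of 0.181% and 0.269%. Thinning left out 45 uninfected and 22 infected cDC-like cells, and 58 and 34 CD4 T-like cells. Median depths were 4573 and 5375 UMIs in cDC-like cells and 3187 and 3014 UMIs in CD4 T-like cells. The cDC class held cluster 14, with 333 uninfected and 161 infected cells, cluster 21, with 134 and 68, and cluster 17.3, with 35 and 34. Clusters 14 and 17.3 scored highest on mature migratory dendritic cell markers and cluster 21 on type 1 markers. None scored highest on type 2 markers, although Cd209a was among the leading genes of cluster 14. Values of this class depended on the naming: with each library clustered on its own, and only 30 infected cells named, the log2 ratio of Iigp1 was 1.75 in place of 5.13, Cxcl10 3.63 in place of 4.59, Cxcl9 0.70 in place of 2.79, Clec4a3 -3.65 in place of -2.58, Egr1 -4.54 in place of -1.85, H2-M2 0.80 in place of -2.23, and the MHC class II median -1.36. Cxcl10 was also 3.99 with predicted doublets kept and 3.92 under the strict cell filter, and Iigp1 was 4.53 with equal weight per cell. The neutrophil genes S100a9, at 236 and 458 CPM, and Ngp, at 4.27 and 106 CPM, were higher in this class of the infected library. However, 1 cell carried 649 of the 691 infected S100a9 UMIs and 156 of the 160 Ngp UMIs. Leaving it out put S100a9 at 28.4 CPM in the infected library, lower than in the uninfected library. Without that cell the log2 ratio of Iigp1 was 5.13 and that of Cxcl10 4.62.

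The third comparison asks how gene lists fixed before the data were examined stood in each class. The interferon-gamma list had a higher median log2 ratio than the type I interferon list in each of the 7 compared classes. Its medians ran from 0.71 (0.65 to 0.84) in NK-like cells to 2.38 (2.31 to 2.44) in monocyte-like cells, with 6 of 21 and 21 of 24 measured members at least 2-fold higher. In neutrophil-like cells the median was 2.33 with 21 of 22, and in cDC-like cells 2.03 with 22 of 23. The type I list ran from 0.39 (0.23 to 0.51) in NK-like cells to 1.24 (1.18 to 1.29) in B-like cells. No measured member of either list was 2-fold lower in any of the 7 classes. Among 10000 random lists matched on expression, as a description of these libraries, the interferon-gamma medians stood at the 100th percentile in each class. The type I median of NK-like cells stood at the 99.95th percentile and was 0.15 with a minimum of 50 CPM. That of cDC-like cells, 0.93, was 0.25 with libraries clustered apart. MHC class I medians were 0.98 in neutrophil-like, 0.76 in monocyte-like and 0.56 in B-like cells. In NK-like cells that median was 0.29, at the 92.8th percentile. The germinal centre list had under 5 measured members in every compared class and gave no median.

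Among the other lists, genes of the cell cycle had positive medians in several classes. Mitosis stood at 1.56 in neutrophil-like cells, where Top2a stood at 42.5 and 156 CPM and 16 of 20 measured members were at least 2-fold higher. The cycling cluster 24 carried 35.8% and 71.8% of the mitosis UMIs of that class, and cluster 7 alone had 3 measured members and gave no median. Mitosis stood at 0.95 in NK-like cells, where cluster 20 carried 79.6% and 89.4% of the UMIs and cluster 8 alone gave 0.99. It stood at 0.50 in CD4 T-like and 0.39 in B-like cells; the B-like median was -0.0475 and the CD4 T-like one 1.36 with libraries clustered apart. In B-like cells the cycling cluster, with 86 uninfected and 160 infected cells, carried 49.1% and 58.4% of the mitosis UMIs, and without it the median was -0.0946 over 5 measured members. Cluster 10 carried 43.2% and 53.1% of those of CD4 T-like cells. In cDC-like cells mitosis had a median of 1.48 and DNA replication 0.38, which with libraries clustered apart were -0.57 and -0.95; mitosis was also 0.85 with predicted doublets kept and 1.22 without the cell rich in neutrophil RNA. In monocyte-like cells NF-kB targets had a median of 1.06 with 7 of 14 at least 2-fold higher, among them Bcl2a1a at 61.8 and 424 CPM, phagocyte receptors and complement 0.66 and heme and iron handling 0.52 with 5 of 14 at least 2-fold higher and 1 lower, where Fth1, the ferritin heavy chain, stood at 3740 and 7569 CPM. Immediate early and heat shock genes had a median of -0.43 there, with 5 of 17 at least 2-fold lower and Fos at 957 and 435 CPM. In CD4 T-like cells, T cell activation genes had a median of 0.58, with 1 of 12 at least 2-fold higher, and Tfh genes 0.35. In NK-like cells secretory pathway genes stood at 0.55 and oxidative phosphorylation at 0.29. Apoptosis genes there had a median of 0.53, but 2 of 11 were at least 2-fold higher and 3 at least 2-fold lower, among the latter the anti-apoptotic gene Bcl2 at 338 and 125 CPM. Some medians given here lay inside the 95% range of random lists: MHC class I, oxidative phosphorylation and cytotoxic effectors in NK-like cells, MHC class II in B-like cells, naive and resting T cell genes in CD4 T-like cells and neutrophil granules in neutrophil-like cells.

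**Figure D2:**
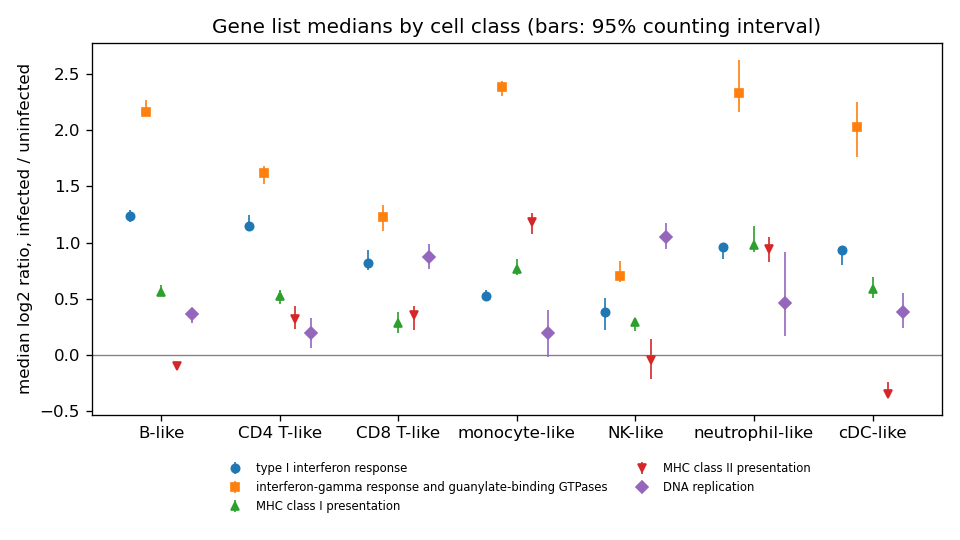
Median log2 ratio (infected over uninfected, vertical axis) of 5 gene lists in the 7 compared cell classes (horizontal axis); bars are 95% counting intervals. Interferon-gamma medians stand between 0.71 and 2.38; MHC class II medians are 1.18 in monocyte-like and -0.34 in cDC-like cells.

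Transcripts of other cell types were compared in the same way. In B-like cells the neutrophil gene S100a9 stood at 129 CPM in the uninfected and 48.3 CPM in the infected library, and in CD4 T-like cells Lyz2 stood at 75.5 and 37.9 CPM. S100a9 was also lower in CD8 T-like cells, at 110 and 30.7 CPM, but stood at 86.1 and 88.3 CPM in NK-like and 108 and 217 CPM in monocyte-like cells. In cDC-like cells it stood at 236 and 458 CPM, and at 28.4 CPM in the infected library without the 1 cell that carried most of it. In monocyte-like cells Lcn2 stood at 49.4 and 10.2 CPM. Haemoglobin Hbb-bs was at 2000 CPM in cluster 5 of the uninfected library and 0.267 CPM in that of the infected library. It was also lower in 6 of the 7 compared classes, at 54.2 and 2.57 CPM in CD4 T-like cells, where 1 uninfected cell carried 183 of 377 UMIs. In neutrophil-like cells it was higher, at 19.4 and 76.4 CPM, with 64 of 70 infected UMIs in 1 cell. The plasma cell gene Jchain was lower in all 7 classes, among them CD4 T-like cells at 48.2 and 4.07 CPM, NK-like cells at 72.9 and 4.31 CPM and monocyte-like cells at 70.6 and 2.43 CPM. A single uninfected cell carried 182 of 335, 134 of 182 and 339 of 393 of those Jchain UMIs. Igkc stood at 1504 and 421 CPM in monocyte-like cells, with 6846 of 8366 uninfected UMIs in 1 cell. The platelet gene Pf4 stood at 1.19 and 1.16 CPM in B-like cells. In monocyte-like cells it had 3 and 24 UMIs and Ppbp 1 and 24, with 21 and 20 of the infected UMIs in a single cell for each gene. Of the sex-linked genes, Ddx3y stood at 84.7 and 73.1 CPM in B-like cells. Plasma-like cells numbered 58 and 24; Ighg2c had 0 UMIs in the uninfected and 839 in the infected library, where 1 cell carried 93.8% of them, and all 540 Ighg1 UMIs of the uninfected library came from 1 cell.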

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

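The T rules, the counting of cluster 5 as B, the use of cluster 8 or cluster 7 alone, the leaving out of the cycling B cluster, the leaving out of cDC with 10 or more Ngp UMIs, and the choice of which results are given here in full were made after seeing the data. Of 80 alternative values of class shares, 64 stayed inside the main 95% interval, as did 676 of 889 for list medians, 664 of 741 for named genes and 11 of 12 for shares of cells with a UMI. Values below are log2 ratios, infected over uninfected, and the cause of each shift was not tested unless stated. The B share, 0.20, was 0.26 with doublets kept, 0.26 with the strict filter, 0.29 with libraries clustered apart, 0.31 with cluster 5, 0.27 with all variable genes and 0.30 by each cell's own markers. Own markers also gave -0.59 for CD4 T, 0.0678 for CD8 T, -0.0786 for monocytes and -0.36 for mixed T. That rule gave the mixed T name to T cells with equal Cd4 and Cd8 counts, including cells with neither. The mixed T share, 2.17, was 0.60 with doublets kept and 0.11 with all variable genes, where a further cluster took the name, and -0.29 under the second T rule, which by construction adds the CD4 T clusters. The first T rule, which by construction adds cluster 18, gave a CD8 T share of 0.12, and in CD8 T medians of 0.52 for type I interferon, 0.86 for interferon-gamma, 0.37 for T cell activation (main -0.11) and -0.0701 for NF-kB targets (main 0.21). With libraries clustered apart the cDC share was -3.97, since only 30 infected cells were named, the macrophage share was 0.17 (main -0.80), and in cDC Iigp1 was 1.75, H2-M2 0.80, type I interferon 0.25, interferon-gamma 1.70, naive T genes 0.14, replication -0.95, mitosis -0.57, secretory genes -1.05, glycolysis -0.76 and oxidative phosphorylation -0.36. Of these, the cDC share, Iigp1 and both interferon lists kept their sign and the others reversed. The same setting gave in B Id3 -1.48, type I interferon 1.14, interferon-gamma 2.07 and mitosis -0.0475. Equal weight per cell gave Id3 in B -1.45, Ifng in CD4 T 1.82, Cxcl9 and Apoe in monocytes 4.72 and -3.84, Klrb1a in NK -1.99, Iigp1 in cDC 4.53, interferon-gamma in CD8 T 1.35, type I interferon in neutrophils 1.08 and in cDC 1.05, and reversed small medians: replication in CD4 T -0.0096, cytotoxic effectors in CD8 T -0.0793, immediate early genes in NK -0.0415 and oxidative phosphorylation in neutrophils -0.0113. Median-ratio scaling gave Id3 in B -1.27, type I interferon 1.34 in B and 0.60 in monocytes, interferon-gamma in monocytes 2.46, MHC class II in B 0.0020 and oxidative phosphorylation in neutrophils -0.0013. A minimum of 50 CPM gave type I interferon 1.17 in B and 0.15 in NK, and interferon-gamma 1.10 in CD8 T, 1.91 in monocytes and 2.01 in neutrophils. No CPM minimum gave interferon-gamma in monocytes 2.53 and immediate early genes in NK -0.0452. Cluster 5 counted as B gave type I interferon 1.16, and leaving out the cycling B cluster reversed mitosis in B to -0.0946 (main 0.39). Cluster 8 alone gave in NK Klrb1a -1.83, type I interferon 0.61 and interferon-gamma 0.85, and reversed cytotoxic effectors to 0.0019 (main -0.16) and Th1 genes to 0.0898 (main -0.26). Cluster 7 alone gave type I interferon in neutrophils 1.04. Leaving out the 1 cDC with 10 or more Ngp UMIs kept Iigp1 at 5.13 and gave mitosis 1.22. Doublets kept gave Ly6a in NK 2.43 and Cxcl10 in neutrophils 5.95, and the strict filter Ifng in CD4 T 2.55. Without thinning the Fcer2a share in B was -0.94. Ccl1 in CD8 T had no finite ratio and was not rerun, and mixed T had no uninfected cells with libraries clustered apart.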

Other observations

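The tests of depth in NK-like cells were chosen after the result was seen. The others were set before their own values were seen, but after the patterns and clusters they concern. Cxcl10 in neutrophil-like cells of the infected library, at 2819 CPM, was weighed against 2 technical sources. Free RNA would give other classes a like level, but the neutrophil level was 32.7 times the median of B-, CD4 T- and CD8 T-like cells, where a ratio under 3 was expected. Doublets with monocyte-like cells would bring monocyte markers, since Cxcl10 stood at 60.9% of the monocyte level; the 8 markers stood at a median of 2.17%, although Ly6c2 reached 23.6%. Both tests argue against these sources for most of the signal. A response of the neutrophils themselves stays open as a hypothesis, since each group is 1 library.

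Interferon-gamma genes were higher in monocyte-like and B-like cells while different clusters held those classes in the 2 libraries, so a shift in makeup alone was a candidate explanation. Within cluster 16, present in both libraries, the list median was 1.97, above the random range of -0.22 to 0.23. Within cluster 6 of the B-like cells it was 2.16, above -0.13 to 0.11. The list was therefore higher within clusters 16 and 6 too, where the proportions of clusters play no part by construction. How much of the class medians a change in those proportions accounts for was not measured. A shift of cell states inside these clusters was not tested. They held 175 of 896 infected monocyte-like and 471 of 5822 infected B-like cells, and the clusters that held most cells of these classes were not tested. Infection or another difference between the libraries stays open and untested.

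NK-like cells of the infected library held more UMIs, at a ratio of medians of 1.62, as did mixed T cells at 1.74 and cluster 9 of the CD8 T-like cells at 1.47. A library deeper in all cells was a candidate explanation, but the highest ratio among the other 6 compared classes was 1.18, which excludes it. The cycling cluster 20 alone is excluded too, since in cluster 8, without it, the ratio was 1.40 (bootstrap interval 1.30 to 1.48). Cell cycle genes were also higher within cluster 8, where replication had a median of 1.22. The cluster held 139 uninfected and 76 infected cells with no UMI of the replication and mitosis lists after thinning. Among these the ratio was 1.26 (1.10 to 1.40). This interval lay above equal depth but spanned the bound set for the test. A cell can lack such a UMI after thinning and still be cycling, so whether cycling cells account for the rest cannot be told. Infection itself, or another difference between the libraries, stays open and untested.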
